A study of Mus musculus with 4 samples.

How the data were processed

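RNA was measured in 4 libraries of mouse bone marrow-derived macrophages, 1 library for each combination of genotype (control, Spic+/+, or Spic−/−) and LPS (0 or 100 ng/ml for 4 h). All cultures had first received hemin for 18 h. The protocol text and the series design give the hemin dose as 40 µM, whereas the sample descriptions give the same number in mM. The sample titles call the knockout a conditional one, and the labels do not give the allele or a Cre driver. Per the labels' protocols, RNA was purified on RNeasy columns and libraries were made with the TruSeq stranded mRNA kit. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 were used with the mm10 build, and no role, order or setting is given there for each tool. The gene annotation behind the values is not given in the sources used here.

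The deposited values were FPKM, 1 file per library, with the same 23284 gene rows in each, no duplicate symbols and no read counts. The sums of FPKM were 500123 in control without LPS, 736818 in control with LPS, 525348 in knockout without LPS and 819232 in knockout with LPS, and genes listed at 0 numbered 8793, 9077, 9075 and 9492. No further normalisation was applied to the main values. From them, log2 ratios of (FPKM + 1) were computed between single libraries. A gene entered a comparison with at least 5 FPKM in at least 1 of its libraries and was counted at 2-fold or more. No test was run: no group has a replicate, and an additive fit of genotype and LPS would have left 1 residual degree of freedom, which is the difference of the responses itself. The minimum, the pseudocount, the threshold, the naming rule, 32 gene lists and all alternatives except 1 were chosen before the data were examined.

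Depth was recovered from the spacing of low FPKM values, since a gene with few fragments takes whole multiples of its value for 1 fragment. The steps of the libraries were compared on genes under 0.3 FPKM. For a check, values were divided by the relative step of their library, and 2419 genes stayed under 0.6 FPKM. Of these, 1916 (79.2%) were whole multiples of the smallest step within a tolerance of 0.02 with divisors up to 6, against 0.331% after scrambling. The relative depth was 100% in control without LPS, 67.8% in control with LPS, 82.8% in knockout without LPS and 51.6% in knockout with LPS. With 807 single-transcript genes of the GENCODE vM21 annotation and an effective length 210 bases below the exonic length, 1 FPKM equalled 15.6, 10.6, 12.9 and 8.06 fragments per kilobase. These are estimates on the authors' own FPKM scale, not counts of reads. One fragment in a 2 kb transcript equalled 0.0358, 0.0527, 0.0432 and 0.0693 FPKM. Exact (Clopper-Pearson) 95% intervals of ratios were computed from the estimated fragments. Ferritin genes took 7.87%, 6.63%, 7.46% and 6.20% of the summed FPKM, and small RNA genes 4.96%, 3.81%, 4.04% and 3.76%. Of 48 genes listed at 0 in one library and at 20 FPKM or more in another, 40 were small RNA genes.

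Spic was named first in every library. For each comparison the 10 highest and 10 lowest ratios were named, leaving out unnamed features and small RNA genes, and for LPS in the knockout the values of the genes named for control. Among LPS-induced genes (at least 2-fold on the mean over both genotypes), the 10 highest and 10 lowest knockout to control ratios with LPS were named. For each list up to 4 members with the largest absolute ratio were named. Some genes that this rule takes are not reported here. List members needed 1 FPKM in at least 1 library, and list genes under other symbols or absent from the files numbered 17. No mitochondrially encoded gene was in the files, so these were not analysed here. Each list was described by its median, by members at 1.5-fold and 2-fold, and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The lists covered cytokines, chemokines, IRF5 targets, interferon-stimulated genes, NF-kB feedback, Toll-like receptor pathway components, effectors, heme and iron, NRF2 targets, red pulp macrophages, alternative activation, MHC class II, cholesterol synthesis, LXR targets, stress responses, heat shock, glycolysis, cell cycle, lysosome and macrophage identity. Further lists held markers of neutrophils, dendritic cells, B cells, T and NK cells, erythroid cells, mast cells and stroma, and sex-linked, housekeeping, ribosomal, Spic-neighbouring and Cre host genes.

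Alternatives changed one choice at a time: a pseudocount of 0.1 or 5, a minimum of 1 or 20 FPKM or none, scaling by median ratios or upper quartiles, a 3-fold threshold, induced genes defined in 1 genotype alone or counted at 2-fold, and list members from 5 FPKM. A further alternative, without small RNA and unnamed genes, was chosen after seeing the data. The counting was tested on simulated libraries drawn with counting error only from the control values with LPS. Their values of 1 fragment differed by 0.874 on the log2 scale, and their depths were not those of the LPS-treated pair. Of 100 genes set 4-fold apart 99 were called, of 100 set 3-fold apart 99, and of 7230 genes set equal none. The simulation holds no variation between cultures, no features as short as small RNA genes and no fragments shared between copies. It therefore gives no rate of false calls for the real pair. Intervals of list medians came from 2000 bootstrap draws over genes. They treat genes as independent and do not cover variation between cultures. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are from RefSeq for GRCm38.p6.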

Results

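Gene expression was measured in mouse bone marrow-derived macrophages, which are macrophages grown in culture from bone marrow progenitors. Cells came from control (Spic+/+) and Spic−/− cultures. Spic encodes Spi-C, an Ets-family transcription factor that heme induces in macrophages. All cultures were pretreated for 18 h with hemin, the oxidised form of heme, and then kept for 4 h with or without lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4. The design asks whether Spi-C lowers part of the genes that Toll-like receptor signalling drives. Each of the 4 combinations of genotype and LPS was represented by 1 library of poly(A) RNA, so no difference has a replicate check, and no test, standard error or p-value is given.

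The values were deposited as FPKM (fragments per kilobase of exon, scaled for library size in a way that the labels do not specify) for 23284 genes in each library. From the spacing of low values, 1 FPKM stood for about 15.6 fragments per kilobase in control without LPS, 10.6 in control with LPS, 12.9 in knockout without LPS and 8.06 in knockout with LPS. A gene with a 2 kb transcript at 5 FPKM then rested on about 140, 95, 116 and 72 fragments. For such a gene in the LPS-treated pair, an observed knockout to control ratio of 1 had a 95% counting interval of 0.723 to 1.37. These intervals cover counting error only, not variation between cultures. Ratios are log2 ratios of (FPKM + 1), which understate the differences of low genes. A gene was counted as higher or lower when it was at least 2-fold apart and reached 5 FPKM in at least 1 library of the comparison.

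Spic itself was lower in knockout than in control in each LPS state. Control cells had 53.1 FPKM without LPS and 406 FPKM with LPS, while knockout cells had 14.98 and 80.8 FPKM. The knockout values were 28.2% of control without LPS and 19.9% of control with LPS, with counting intervals of the ratio of 0.248 to 0.32 and 0.186 to 0.213. The Spic FPKM with LPS was 7.64-fold that without LPS in control cells and 5.39-fold in knockout cells. Spic lies on chromosome 10 at 88675269 to 88683023 (GRCm38.p6), on the minus strand, and its annotated transcript has 6 exons and 1763 exonic bases. The values are per gene, so they do not show which exons the remaining fragments in the knockout libraries came from.

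**Figure D1:**
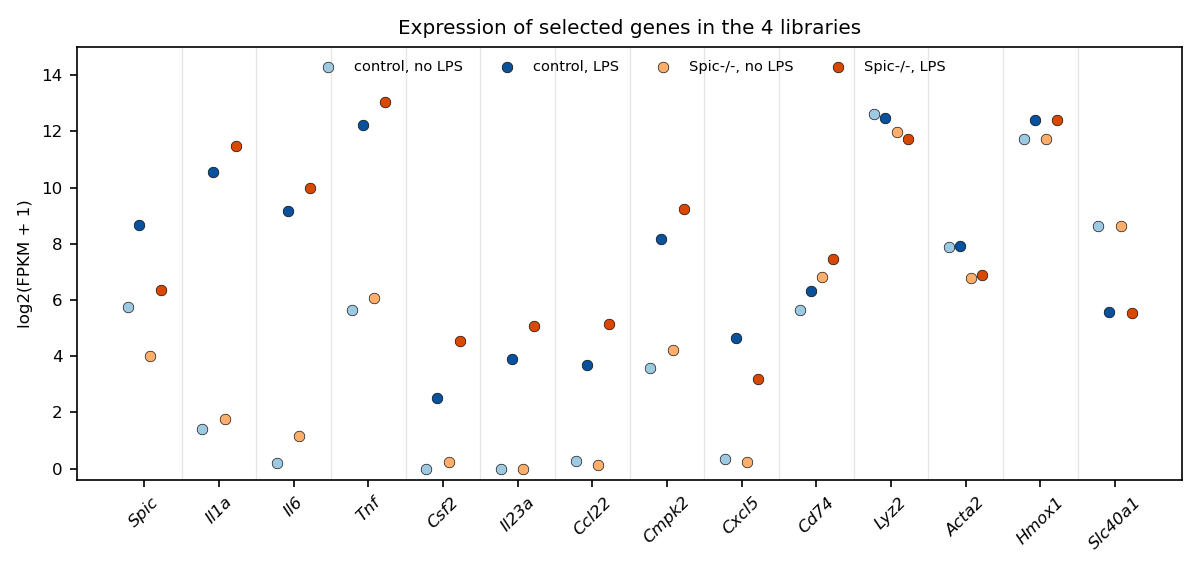
Log2(FPKM + 1) of 14 genes in the 4 libraries, each point 1 library and each colour 1 combination of genotype and LPS. Within each LPS state Spic sits lower in knockout than in control. Il1a, Il6, Tnf and Csf2 sit highest in knockout with LPS, and within each LPS state Hmox1 and Slc40a1 lie at about the same height in both genotypes.

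In control macrophages, LPS went with much higher levels of cytokine and chemokine genes. Il1b, which encodes interleukin 1 beta, stood at 1.37 FPKM without LPS and 5779 FPKM with LPS, a log2 ratio of 11.25. It was followed by the neutrophil chemokine gene Cxcl1 (9.40), the cyclooxygenase 2 gene Ptgs2 (9.24), Il1a (9.12), Il6 (8.98), Cxcl10 (8.66) and Cxcl2 (8.37). Socs3, a feedback inhibitor of cytokine signalling (8.26), Gbp5 (7.72) and Il27 (7.62) completed the 10 highest. The lowest ratios belonged to Arl11 (−3.67), Cd300lb (−3.58) and the oxysterol receptor gene Gpr183, which stood at 10.8 FPKM without LPS and 0.172 with LPS. Gcnt1 (−3.28), the cyclin D1 gene Ccnd1 (−3.25), the urokinase gene Plau (−3.25), Sesn1 (−3.21), Lpar6 (−3.16) and Susd3 (−3.15) were also among the lowest. In all, 992 of 8050 genes were higher and 523 lower with LPS. Higher genes made up 65.5% of these calls as deposited and 36.9% after upper-quartile scaling, which moved the median ratio of all genes from 0.11 to −0.28.

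Among the gene lists fixed before the data were examined, 19 of 21 inflammatory cytokine genes were at least 2-fold higher with LPS in control cells and none was lower, with a median log2 ratio of 4.81. In addition to Il1b, Il1a and Il6, Il27 stood at 499 FPKM with LPS against 1.54 without. Of 21 chemokine genes, 18 were at least 2-fold higher (median 3.71), including Cxcl3 (7.49). Of 11 genes reported as targets of the transcription factor IRF5, each of which is also a member of the cytokine or chemokine list, all were at least 2-fold higher (median 6.60), Tnf at 6.60 among them. The interferon list, with 30 of 34 genes at least 2-fold higher, had a median of 2.76, and Ifit1 (5.51), Oasl1 (5.33) and Mx2 (5.06) stood high in it. Regulators of NF-kB and Toll-like receptor signalling were higher in 25 of 26 cases (median 3.56), with Dusp2 at 6.61 and Tnfaip3, which encodes the inhibitor A20, at 5.48. Of the 27 antimicrobial and effector genes, 26 were at least 2-fold higher (median 3.11), among them Irg1, the itaconate-producing enzyme gene, at 7.13. The 27 Toll-like receptor pathway components were mixed, with 9 higher and 2 lower (median 0.61): Cd14, the LPS co-receptor gene, was at 4.94, whereas the nucleic acid sensor genes Tlr9 and Tlr13 were at −1.67 and −1.87.

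Metabolic and resident macrophage genes gave smaller medians. Glycolysis and hypoxia genes had a median of 0.87, with 10 of 23 at least 2-fold higher and Pfkfb3 at 4.36. The list of MHC class II and costimulation genes had a median of 0.58, with Cd40 (5.90) and Cd274 (3.57) highest in it. Cholesterol synthesis genes had a median of −0.38, with Dhcr7 at −1.37, and genes of LXR targets and lipid efflux had −0.14, with Abcg1 at −1.75. The median was −0.35 for alternative activation genes, with Stab1 at −1.66, −0.21 for lysosome genes, with Tfeb at −2.11, −0.22 for macrophage identity genes, −0.08 for NRF2 targets and −0.30 for cell cycle genes. In the heme and iron list the members went both ways: the iron exporter gene Slc40a1 stood at 395 FPKM without LPS and 46.7 with LPS, the ferroxidase gene Cp at 5.82 and 45.3, and the heme oxygenase gene Hmox1 at 3396 and 5423. The median of that list was 0.13, and it took the other sign after upper-quartile scaling. Sign changes of the same kind under that scaling held for the medians of red pulp macrophage genes (0.00), stress response genes (0.16), heat shock proteins (0.25), housekeeping genes (0.25) and ribosomal protein genes (0.19).

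Knockout macrophages gave nearly the same ranking of genes with LPS. There, Il1b stood at 6.70 FPKM without LPS and 8589 with LPS (log2 ratio 10.12), Il1a at 2.41 and 2817 (9.69), and Il6 at 1.23 and 1004 (8.82). The ratio was 8.99 for Cxcl1, 8.59 for Ptgs2, 8.72 for Cxcl10 and 7.53 for Socs3, and at the other end −3.78 for Arl11, −4.14 for Cd300lb and −3.34 for Gpr183. In the knockout 1109 of 8098 genes were higher and 627 lower, with higher genes at 63.9% of calls as deposited and 35.1% after upper-quartile scaling. List medians were 4.82 for cytokines, 3.71 for chemokines, 6.98 for IRF5 targets, 3.02 for the interferon list, 3.60 for NF-kB feedback genes and 3.24 for effector genes.

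The LPS responses of the 2 genotypes share no library and were compared across 8272 genes, which are not independent replicates. Pearson's r was 0.896 and Spearman's rho 0.954, and without small RNA and unnamed rows they were 0.977 and 0.962 over 7772 genes. Both responses were at least 2-fold higher for 934 genes, where independent lists would share 137, and both lower for 471, where independent lists would share 42.8. On the scale of log2(FPKM + 1), 5 genes had ratios beyond 1 in opposite directions: Ass1, Akr1b3 and the small RNA genes Mir1892, Snora3 and Snora34, the last 3 named after their values were seen. All but Ass1 were listed at 0 in at least 1 library, and with a pseudocount of 5 FPKM the knockout ratios of Ass1 (−0.64) and Akr1b3 (−0.54) were under 2-fold.

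**Figure D2:**
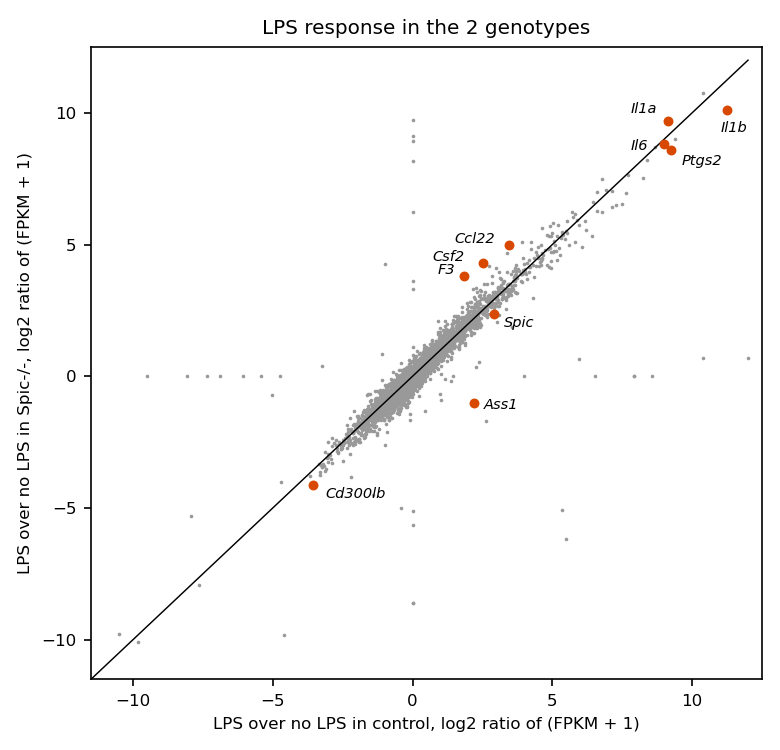
Log2 ratio of LPS over no LPS in control (horizontal axis) and knockout (vertical axis) for the 8272 genes at 5 FPKM or more in at least 1 library, each point 1 gene, with the diagonal marking equal ratios. Named genes are in orange; Csf2, F3 and Ccl22 lie above the diagonal and Ass1 lies below it, at 2.18 in control and −1.003 in knockout, and points far from the diagonal include small RNAs listed at 0 in 1 library.

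Without LPS, knockout and control macrophages differed at few genes. Among the genes with the highest knockout to control ratios, Il1b was at 1.37 FPKM in control and 6.70 in knockout, Ptgs2 at 1.82 and 5.93, and Ch25h, the cholesterol 25-hydroxylase gene, at 2.35 and 8.78. The counting interval of the Il1b ratio was 3.06 to 7.74. Among those with the lowest ratios were Thbs1 at 109 FPKM in control and 43.03 in knockout, the smooth muscle myosin light chain gene Myl9 at 64.1 and 25.96, and the proteoglycan gene Ogn at 31.3 and 12.5. In all, 38 of 7762 genes were higher and 32 lower, or 25 and 19 without small RNA and unnamed rows. The share of higher genes among the calls was 54.3% as deposited and 44.1% after upper-quartile scaling, which moved the median of all genes from 0.07 to −0.02. The central 95% of genes had ratios from −0.37 to 0.49. With a pseudocount of 5 FPKM the ratios of Il1b (0.88), Ptgs2 (0.68) and Ch25h (0.91) were under 2-fold.

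The largest genotype ratios without LPS included genes that share sequence with other loci, whose values are therefore uncertain. Ugt1a6b, a glucuronosyltransferase gene that shares exons with its family, had a ratio of 2.55, and the pseudogene Atp6v0c-ps2 had 2.34 while its parent gene Atp6v0c, a proton pump subunit gene, had −1.49. The pseudogene Rpl34-ps1 (1.64) and the ribosomal protein gene Rps27 (−4.19) belong to the same kind. The remaining members of the 10 highest were Snhg9 (1.61), Ass1, an enzyme gene of arginine synthesis (1.52), Dppa3 (1.51) and Wdfy1 (1.42). Snhg9 is uncertain as well, since the small RNA gene Snora78 lies within its span. Snora78, named after its values were seen, went the other way, at 7.03 FPKM in control and 0 in knockout. Assignment of fragments between them was not tested. The 10 lowest also held Spic (−1.76), BC055004 (−1.71), D4Bwg0951e, now called Lurap1l (−1.27), and Apobec1, which encodes the apolipoprotein B mRNA editing enzyme (−1.17). Among these, Ass1 (0.91), Dppa3 (0.79), Wdfy1 (0.85), BC055004 (−0.88) and D4Bwg0951e (−0.75) were under 2-fold with a pseudocount of 5 FPKM.

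Among the fixed lists, chemokine genes had the highest median without LPS, 0.50, with 8 of 21 members at least 1.5-fold higher, including Cxcl3 (1.18), Ccl12 (1.08) and Cxcl14 (1.07), and 1 lower, Cx3cl1 (−0.63). The interferon list had a median of 0.48, with 33 of 34 genes above 0, 11 at least 1.5-fold higher and none lower. Ifit3 (0.80) and Zbp1 (0.79) were its highest. Effector genes had a median of 0.31, with 10 of 27 at least 1.5-fold higher, among them Irg1 (1.02), and 1 lower, F3 (−0.64). IRF5 targets had 0.35, NF-kB feedback genes 0.24, with Traf1 at 1.04, and cytokine genes 0.17, with Il1rn, the interleukin 1 receptor antagonist gene, at 1.02. The medians of chemokine, interferon, NF-kB feedback and effector genes lay above all of 10000 random lists of the same size matched on expression, and that of cytokines at the 99.4th percentile, as a description of these libraries. In the same pair of libraries the markers of stromal and endothelial cells had a median of −0.59.

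MHC class II and costimulation genes had a median of 0.27, led by Cd74, the invariant chain gene, at 49.2 FPKM in control and 111 in knockout, H2-Aa at 17.8 and 35.1, and H2-Ab1 at 17.3 and 34.2. The stromal and endothelial markers, whose median lay below all of the random lists, included 6 of 12 members at least 1.5-fold lower. Acta2, the smooth muscle actin gene, stood at 237 FPKM in control and 109 in knockout, Col1a1 at 84.04 and 47.3, and Sparc at 109.9 and 62.96. Macrophage identity genes had a median of 0.19, while the lysozyme genes within that list were lower: Lyz2 stood at 6340.4 FPKM in control and 4014 in knockout, and its adjacent paralog Lyz1 at 716 and 459. The median was 0.20 for LXR targets, 0.19 for glycolysis genes, 0.14 for Toll-like receptor pathway components, with Cd14 at 1.03, 0.10 for lysosome genes, −0.10 for cell cycle genes and −0.06 for NRF2 targets. After upper-quartile scaling the sign changed for the medians of alternative activation genes (0.15), cholesterol synthesis genes (0.08), heat shock proteins (0.05), stress response genes (0.04) and red pulp macrophage genes (0.04).

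With LPS, 4 of 21 cytokine genes and 1 of 34 interferon-related genes were at least 2-fold higher in knockout, and 11 and 13 at least 1.5-fold higher. Csf2, the gene of the growth factor GM-CSF, was at 4.69 FPKM in control and 22.2 in knockout, a ratio of 4.74 with a counting interval of 3.16 to 7.52. Tnf was at 4840.3 and 8392 FPKM, Il1a at 1487 and 2817, Il6 at 577 and 1004, and Il23a, a subunit gene of interleukin 23, at 14.01 and 32.8. The chemokine gene Ccl22 was at 11.9 FPKM in control and 33.9 in knockout, whereas Cxcl5, another chemokine gene, was at 24.3 and 8.05. In all, 37 of 7509 genes were higher and 30 lower, or 27 and 15 without small RNA and unnamed rows. Higher genes were 55.2% of calls as deposited and 43.8% after upper-quartile scaling, which moved the median of all genes from 0.09 to −0.02. The central 95% of genes had ratios from −0.49 to 0.60.

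The 10 highest genotype ratios with LPS were led by Rpl26, a ribosomal protein gene listed at 0 in the other 3 libraries and at 8.96 FPKM in this one, which is uncertain because copies of it exist elsewhere in the genome. They continued with Ugt1a6b (2.49), Csf2 (2.03), Niacr1, the niacin receptor gene now called Hcar2 (1.48), Shisa3 (1.48), Ccl22 (1.43), the uridine phosphorylase gene Upp1 (1.38), the tissue factor gene F3 (1.32), Wdfy1 (1.32) and Tnfsf13, which encodes the B cell factor APRIL (1.31). The 10 lowest included Rps27 (−4.25), Akr1b3, listed at 0 in knockout with LPS and at 5.23 FPKM in control with LPS, Spic (−2.32), Ass1 (−1.66), Cxcl5 (−1.48), Apobec1 (−1.28), Ocel1 (−1.14), Apoo-ps (−1.11) and the pentraxin gene Ptx3 (−1.10). With a pseudocount of 5 FPKM, Wdfy1 (0.82), Tnfsf13 (0.95), Ocel1 (−0.74) and Apoo-ps (−0.57) were under 2-fold.

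Of 21 cytokine genes, 19 were above 0 in this pair, 11 were at least 1.5-fold higher and 4 at least 2-fold higher, with a median of 0.69 that lay above all 10000 matched random lists. Besides Csf2 and Il23a, Osm, the oncostatin M gene, was at 4.995 FPKM in control and 13.4 in knockout, and Il12a at 1.595 and 4.43. Csf1 and Tnfsf9 were the 2 members below 0, at −0.43 and −0.35. With a pseudocount of 5 FPKM the ratios of Osm (0.88), Il23a (0.99) and Il12a (0.52) were under 2-fold, and that of Il12a also after upper-quartile scaling (0.94). All 34 interferon-related genes were above 0 (median 0.50), 13 were at least 1.5-fold higher and none lower. The only one at 2-fold or more was Cmpk2, which was under it after median-ratio (0.97) and upper-quartile scaling (0.92) alike. Cmpk2 stood at 289.5 FPKM in control and 594 in knockout, and the antiviral gene Rsad2 at 765 and 1384. IRF5 targets had a median of 0.57 with all 11 above 0, chemokines 0.43 with Ccl22 and Cxcl11 (1.01) at least 2-fold higher and Cxcl5 at least 2-fold lower (Cxcl11 was at 0.91 with a pseudocount of 5 FPKM, 0.94 after median-ratio and 0.89 after upper-quartile scaling), and effector genes 0.37 with 6 of 27 at least 1.5-fold higher and 1, Ass1 (−1.66), lower. Regulators of NF-kB and Toll-like receptor signalling had a median of 0.19, with 2 of 26 at least 1.5-fold higher (Cish, 0.78, and Traf1, 0.65) and none lower. Toll-like receptor pathway components had 0.21, with Tlr1 at 0.83 and the Irf5 gene itself at 153 FPKM in control and 217 in knockout. In the same libraries the stromal and endothelial markers had a median of −0.62.

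Because most LPS-induced genes had ratios above 0 in this pair, the induced genes were also set against each other. Of 1050 genes induced at least 2-fold on the mean of both genotypes, 123 (11.7%) were at least 1.5-fold higher in knockout with LPS and 21 (2.0%) lower, with a median of 0.23 and 83.8% of genes above 0. After upper-quartile scaling, 71 induced genes were higher and 28 lower by this measure. Of 579 genes at least 2-fold lower with LPS, 9 were higher and 15 lower (median −0.02, 44.2% above 0). Of 6643 other genes, 89 were higher and 107 lower (median 0.07, 65.0% above 0). Without LPS the induced genes had a median of 0.13, with 73 higher and 11 lower by 1.5-fold. Against random lists drawn from induced genes, the 19 induced cytokine genes (median 0.69, random 0.25) and the 30 induced interferon-related genes (median 0.48) lay above all lists. Effector genes lay at the 99.4th percentile, chemokines at the 96.6th and NF-kB feedback genes, with a median of 0.18, at the 6.0th.

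Among the induced genes, the highest ratios beyond those named above belonged to Hdc, the histidine decarboxylase gene (7.13 FPKM in control and 18.8 in knockout), Osm (1.27) and Mycl1, now called Mycl (1.24). The lowest besides Spic, Cxcl5 and Ptx3 included S100a8, a calprotectin gene of myeloid cells at 214 FPKM in control and 114 in knockout, the metallothionein gene Mt2 (−0.78), Etv3 (−0.70), Cx3cl1 (−0.67), Rnd1 (−0.66) and Pdgfra (−0.61), a receptor gene of mesenchymal cells. The stromal list, to which Pdgfra belongs, had its median of −0.62 below all matched random lists, with 8 of 12 members at least 1.5-fold lower and Acta2 at 243 FPKM in control and 118 in knockout.

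**Figure D3:**
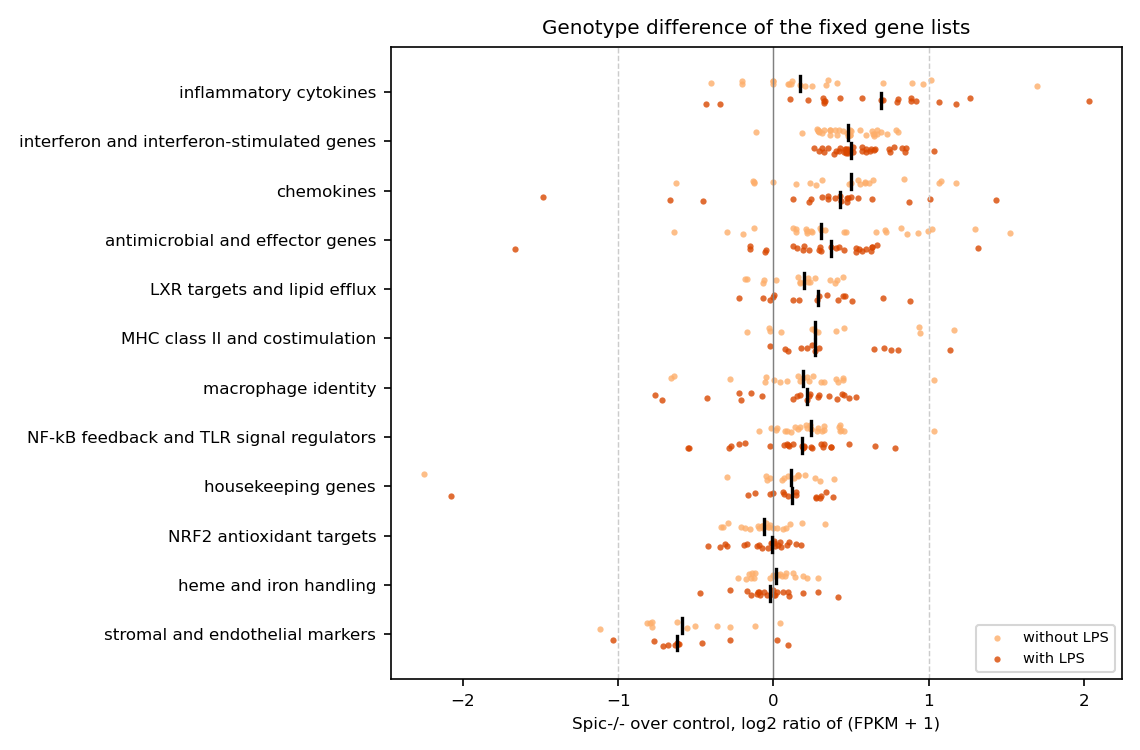
Knockout over control log2 ratio of (FPKM + 1) for the members of 12 fixed gene lists, without LPS (light points) and with LPS (dark points); each point is 1 gene, black bars are medians, dashed lines mark 2-fold, and points are spread vertically for legibility. Cytokine genes have a median of 0.17 without LPS and 0.69 with LPS, interferon-related genes 0.48 and 0.50, and stromal markers −0.59 and −0.62.

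Heme and iron genes stood at close levels in the 2 genotypes. Hmox1 was at 5423 FPKM in control and 5426 in knockout with LPS, and Slc40a1 at 46.7 and 45.4. None of the 20 members was 1.5-fold apart in either LPS state, and the medians were 0.02 without LPS, where scaling changed its sign, and −0.02 with LPS. Of the 22 NRF2 targets none was 1.5-fold apart with LPS either (median −0.01), and the same held for the 21 cholesterol synthesis genes (−0.01) and the 22 lysosome genes (0.12). LXR targets had a median of 0.29, with Mylip at 0.88 and Abcg1 at 0.71. MHC class II and costimulation genes had 0.27, with Cd74 at 78.8 FPKM in control and 175 in knockout. Macrophage identity genes had 0.22, glycolysis and hypoxia genes 0.27, red pulp macrophage genes 0.15 and stress response genes 0.14. Alternative activation genes (0.09), cell cycle genes (0.07) and heat shock proteins (0.07) had medians that changed sign after upper-quartile scaling.

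Lists that check the samples gave the following values. The medians without and with LPS were 0.11 and 0.12 for housekeeping genes, 0.04 and 0.03 for ribosomal protein genes, where scaling changed the sign of both, and −0.12 and −0.13 for 4 sex-linked genes, all of them Y-linked and detected in the 4 libraries. The 10 neighbours of Spic above the list minimum on chromosome 10 had 0.17 and 0.10, the second of which changed sign with scaling, and none was 1.5-fold apart. Most markers of other blood cells in the files stayed under 1 FPKM in all 4 libraries, and the medians cover those above it. The 6 of 15 neutrophil markers above it had medians of 0.02 (sign changed by scaling) and −0.34, the 4 of 15 dendritic cell markers −0.42 and 0.18 (sign changed by scaling), the 3 of 10 B cell markers −0.32 and −0.30, the 2 of 16 T and NK cell markers 0.16 and 0.41, and the 2 of 15 erythroid and megakaryocyte markers −0.05 and −0.33. With LPS in control cells the neutrophil list had a median of 0.74, the dendritic cell list 0.66, the erythroid list 1.13, the B cell list −0.45, the T and NK cell list 0.07 and the stromal list 0.15, the last 2 of which changed sign after upper-quartile scaling. Of 11 mast cell markers in the files, only Hdc reached 1 FPKM in any library, at 0.15 and 1.28. The 6 genes that commonly host Cre drivers, which include Lyz2, had 0.19 and −0.15.

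The difference between the LPS responses was at least 2-fold larger in knockout for 31 of 8272 genes and smaller for 37, or 12 and 15 without small RNA and unnamed rows, and it has no residual to test it against. Among the larger responses, F3 differed by 1.96, Csf2 by 1.78, Ccl22 by 1.56, Shisa3 by 1.45, Upp1 by 1.31, Il23a by 1.17, Osm by 1.17, Il1f6 by 1.15 and Hdc by 1.13, in addition to the uncertain Rpl26. Csf2 was not detected in control without LPS. For Il23a and Il1f6 the difference was the same number as the genotype ratio with LPS, because their values without LPS were equal in the genotypes. Exactly equal values are what genes without detected fragments in either untreated library give, so they are not a measured absence of a genotype difference. With a pseudocount of 0.1 FPKM the differences of Csf2 (0.70) and Hdc (0.48) were under 2-fold, and with 5 FPKM so were those of Il23a (0.99), Osm (0.84), Il1f6 (0.72) and Hdc (0.94). The smaller responses were led by Akr1b3, listed at 0 in control without LPS and in knockout with LPS, Ass1 (−3.19), Rpl34-ps1 (−1.90), Rmnd1 (−1.76), Rpl30 (−1.67), Dppa3 (−1.63), the uncertain Snhg9 (−1.61), Fam100b, now called Ubald2 (−1.56), Apoo-ps (−1.52) and Cxcl5 (−1.36). The differences of Rmnd1 (−0.93), Dppa3 (−0.82), Fam100b (−0.79) and Apoo-ps (−0.74) were under 2-fold with a pseudocount of 5 FPKM. The list median was 0.38 for cytokines, −0.11 for chemokines, 0.07 for the interferon list, −0.09 for NF-kB feedback genes and −0.15 for effector genes.

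The genotype differences in the 2 LPS states also share no library. Whether the cultures of a genotype came from the same marrow is not known here. Sharing between the LPS states is therefore not a replicate of the genotype difference. Across 8272 genes Pearson's r was 0.284 and Spearman's rho 0.416, or 0.540 and 0.428 without small RNA and unnamed rows. Genes higher in knockout in both states numbered 8, where independent lists would share 0.189, and genes lower in both numbered 10, where independent lists would share 0.120, while 6 went in opposite directions (Ass1, Akr1b3, 3 small RNA genes and 1 unnamed gene), all but Ass1 listed at 0 in at least 1 library. Besides small RNAs and the genes with copies named above, the higher genes were Cd74, the inhibitory lectin receptor gene Siglece (1.23 and 1.19), Tnfsf13 (1.19 and 1.31), Wdfy1 (1.42 and 1.32) and Ugt1a6b. Atp6v0c-ps2, counted among the 8, was at 1.09 with LPS and at 0.98 after upper-quartile scaling. The values of Siglece (0.82) without LPS and of Tnfsf13 (0.95 and 0.95) and Wdfy1 (0.85 and 0.82) in both states were under 2-fold with a pseudocount of 5 FPKM. The lower ones included Spic, Apobec1, Ogn, Acta2 and the smooth muscle gene Tagln (−1.001 and −1.04). Under the same pseudocount Ogn with LPS (−0.90) and Tagln in both states (−0.95 and −0.99) were under 2-fold. Siglece, Tagln, Hmox1, Tlr9, Tlr13, Irf5, Csf1, Tnfsf9, Cx3cl1 without LPS, and the genotype values of Tnf lay outside the naming rule and were chosen after their values were seen.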

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

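The test of a second stromal list was planned before its result was seen. All other tests in this part were chosen only after the result was seen. The bootstrap intervals redraw genes within a single pair of libraries. They treat co-regulated genes as independent and do not cover variation between cultures, so what they argue against holds for these libraries only.

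For 4 of the named genes, the ratio had opposite signs in the groups compared by at least 1.5-fold each; the difference was not tested, since each group holds 1 library. Ass1 had an LPS log2 ratio of 2.18 in control and −1.003 in knockout, and a knockout to control ratio of 1.52 without LPS and −1.66 with LPS. F3 had a knockout to control ratio of −0.64 without LPS and 1.32 with LPS, and the former rests on 1.496 and 0.602 FPKM and was −0.21 with a pseudocount of 5. Akr1b3, listed at 0 in control without LPS and in knockout with LPS, had LPS values of 2.64 in control and −1.71 in knockout and genotype values of 1.71 and −2.64 on the scale of log2(FPKM + 1), which are not folds. Its LPS value in knockout was −0.54 and its genotype value without LPS 0.54 with a pseudocount of 5, both under 1.5-fold. Rpl30 had 0.98 and −0.69 with LPS, and 0.84 and −0.83 by genotype, of which the LPS value in knockout was −0.52 with a pseudocount of 5. Akr1b3 and Rpl30 have near-identical copies elsewhere in the genome.

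Of 21 cytokine genes, 11 were at least 1.5-fold and 4 at least 2-fold higher in knockout with LPS (median 0.69). A shift of library scaling would leave the list at the median of all genes, but it lay 0.60 above it (bootstrap interval 0.24 to 0.80). A larger macrophage share would move macrophage identity genes alike, yet the cytokine median lay 0.46 above that of the 19 such genes other than Lyz1 and Lyz2 (0.04 to 0.69), and 0.48 above that of all 21 (0.09 to 0.78). Counting error is argued against, for the list's median, by the 19 members with at least 30 estimated fragments in both libraries. Their median was 0.57 (0.32 to 0.80), and 9 of them were at least 1.5-fold higher. The members left out, Csf2 (29.3 fragments in control) and Il12a (17.9), were among the 4 at 2-fold or more. Loss of Spi-C and an unrelated difference between the cultures cannot be told apart, because each genotype and LPS state holds 1 library.

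Interferon-related genes had knockout to control medians of 0.48 without LPS and 0.50 with LPS, with 11 and 13 of 34 at least 1.5-fold higher and 0 and 1 at least 2-fold higher. With LPS their median lay 0.27 above that of macrophage identity genes other than Lyz1 and Lyz2 (0.15 to 0.44), and 0.28 above that of all of them (0.19 to 0.61), which argues against a larger macrophage share. Without LPS it lay 0.41 above the median of all genes (0.31 to 0.50), so the difference was also present in the pair of libraries without added LPS. A difference in Spi-C or in the history of the single cultures stays open.

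Of 12 stromal and endothelial markers, 6 were at least 1.5-fold lower in knockout without LPS and 8 with LPS. Fewer stromal cells in the knockout cultures is a candidate explanation: a second list, fixed before it was measured and sharing none of its 33 measured members with the other lists, had medians of −0.68 without LPS and −0.57 with LPS, with 30 and 31 members below 0. Its most abundant genes were Bgn (186 FPKM in control and 113 in knockout without LPS), Igfbp7 (91.7 and 61.3) and Tgfbi (93.5 and 155), and Tgfbi and Cav1, which macrophages can also express, were the 2 members at least 1.5-fold higher without LPS. Library scaling is argued against, since the first list lay at −0.66 relative to the median of all genes in the LPS state where the gap was smaller (upper bound −0.39). Lower expression of these genes per cell was not tested apart from fewer cells.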

How the results depend on the processing

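The alternative without small RNA and unnamed genes was chosen only after the results were seen; the others were planned. No gene value at 2-fold or more changed sign under any alternative. Of 160 list medians, 35 changed sign under a scaling, and upper-quartile scaling turned the balance of LPS calls, as given below. No paired analysis was possible because each group holds 1 library. Of 112 counts under an alternative, 72 stayed within 1.5-fold of the reported count and 40 did not, and 1 of 16 correlations moved by more than 0.1. Of 795 list medians and 5200 gene values under an alternative, 771 and 4957 stayed close in size. Of 80 calls at the ranked ends of the comparisons, 78 stayed at 2-fold with a pseudocount of 0.1, 60 with 5, and 80 under both scalings. Counting the genes that the rule names, also from lists, in every comparison, 12 values at 2-fold were under it after median-ratio scaling and 34 after upper-quartile scaling. Under both were Cmpk2 and Cxcl11 with LPS and Il1rn, Irg1, Traf1 and Cd14 without LPS. A pseudocount of 5 also ended further calls of such genes. Among them were Cxcl3 (0.76), Ccl12 (0.75) and Cxcl14 (0.88) in knockout without LPS, Mycl1 (0.93) in knockout with LPS, and Dhcr7 (−0.63) for LPS in control. Stricter thresholds and minimums give fewer genes, and lower minimums more, by construction; for the other settings the cause was not tested.

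With a pseudocount of 0.1, 47 LPS responses were larger and 63 smaller in knockout. With a pseudocount of 5, genes lower with LPS numbered 229 in control and 263 in knockout, genes higher and lower in knockout without LPS 19 and 21, genes higher in knockout with LPS 21, and induced genes lower in knockout 13. With a minimum of 1 FPKM, 51 genes were lower in knockout with LPS, and 47 responses were larger and 67 smaller. With no minimum these were 51, 49 and 68. With a minimum of 20 FPKM, genes lower with LPS numbered 183 in control and 210 in knockout, genes higher in knockout 25 without and 23 with LPS, and smaller responses 24. With upper-quartile scaling, 683 genes were higher and 1167 lower with LPS in control, 715 were higher and 1322 lower in knockout, and 71 induced genes were higher in knockout with LPS. At 3-fold, LPS gave 570 higher and 177 lower genes in control and 620 and 213 in knockout, and the knockout had 17 higher and 16 lower genes without LPS and 11 and 18 with LPS. With induced genes defined in the knockout alone, 12 were lower, and counted at 2-fold 28 were higher and 11 lower. Without small RNA and unnamed genes, the knockout had 25 higher and 19 lower genes without LPS and 15 lower with LPS, 12 larger and 15 smaller responses, 11 induced genes lower, and a correlation of genotype ratios of 0.540. The alternative of summing repeated symbols had nothing to sum. Depth limits the genes near 5 FPKM, where ratios between 0.723 and 1.37 in the LPS-treated pair lie within counting error for a 2 kb transcript.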

Other observations

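All tests in this part were chosen only after the result was seen.

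A few list members not described above follow. C1qa, a subunit gene of complement C1q, was at 494 FPKM in control and 685 in knockout without LPS, and C1qb at 778 and 1055, both less than 1.5-fold apart. Fn1, the fibronectin gene, was at 59.7 and 32.8. The fractalkine receptor gene Cx3cr1 had a genotype log2 ratio of 0.91 without LPS and −0.06 with LPS, the latter within the spread of most genes. The small heat shock protein genes Hspb1 and Cryab had −0.81 and −0.75 without LPS, alongside the stromal markers at −0.59. These genes were chosen after their values were seen.

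The proton pump gene Atp6v0c and its pseudogene Atp6v0c-ps2 had opposite genotype ratios. Assignment of shared fragments to one copy or the other may account for this, since the sum of both was 726 and 715 FPKM in control and 811 and 813 in knockout, and its log2 ratio was at most 0.18 between genotypes. Which copy the fragments came from needs the reads.

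Lyz2 in knockout was 63.3% of control without LPS and 60.8% with LPS, and its neighbour Lyz1 64.1% and 59.0%. Lyz2 and Lyz1 lie on chromosome 10, as Spic does, starting at 117277541 and 117287795. They were under 2-fold apart, so the test of a chromosome segment given below did not cover them. One hypothesis is that 1 of the Lyz2 copies was interrupted, as in lines with Cre placed in that gene, which the labels do not state. Interruption of Lyz2 alone would not lower Lyz1 as well, unless fragments of the paralogs were assigned to the wrong gene, which was not tested. Relative to the median of macrophage identity genes other than Lyz1 and Lyz2, the ratio of Lyz2 lay at −0.87 without LPS and −0.95 with LPS (−0.85 and −0.93 relative to all of them), which could reflect such a loss or lower expression, and these cannot be told apart because the labels give no driver and gene-level values do not show a lost copy.

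A segment of chromosome 10 carried along with the Spic allele could place genes that differ in both LPS states near Spic. Of 17 such genes with a position, 1 lay within 20 Mb of Spic and the 17 lay on 14 chromosomes, which argues against a segment as the source of most of them. The 1 gene was the small RNA gene Mir678, named after its values were seen. It was listed at 0 in both control libraries and at 1292 FPKM without and 2771 with LPS in knockout. Its annotated span, 76207326 to 76207409, is shorter than the 210 bases taken off the exonic length in the depth estimate. Its FPKM therefore cannot be turned into fragments and may rest on few of them. A segment stays open for this gene.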
